A study of Homo sapiens with 34 samples.

How the data were processed

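Gene expression was measured on Affymetrix arrays with 54675 probe sets in 34 human skin samples. The authors deposited log2 probe set summaries. Per the labels they were made with GCRMA, whose version and settings, and any batch step, are not stated. No columns are identical (highest correlation between samples 0.983). The values were used as deposited, without further scaling.

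Groups were taken from the sample labels. All 6 pairs of groups were compared. No term for protocol or material could be fitted, since each belongs to whole groups, and the labels name neither batches nor dates. After the data were seen, the nevi above the mean of the 12 nevi in both the hybridization controls and the 3' to 5' difference (4 nevi, 2 of each group) were taken as a set of high control signal. The fit was repeated with that set as a block, without it, and with the block and without the 2 common nevi whose titles follow another scheme. Differences of list scores were also computed within the sets, with exact permutation within them, and splits were repeated within the sets. Counts were also compared with those of all 210 choices of 2 common and 2 dysplastic nevi, left out or taken as the block.

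Of the probe sets, 41097 were paired with 1 gene by the annotation, 1801 with several and 11777 with none, and the last 2 kinds were left out. Of the 41097, 68 paired with sex-specific genes and 6 control probe sets were left out, and 41023 were used. The other 56 of the 62 control probe sets lie among those with several genes or none. For each of 19734 genes the probe set with the highest mean over all samples was used, and the 17910 genes with a log2 value of at least 4 in at least 5 samples were tested. A linear model with the 4 groups was fitted to all samples with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 30 residual degrees of freedom, two-sided, Benjamini-Hochberg over genes within a comparison). A gene was counted as changed at an adjusted p under 0.05 and at least a 2-fold difference (1 on the log2 scale). A gene was stepwise when it passed the adjusted p from common to dysplastic nevi and from dysplastic nevi to melanoma in the same direction.

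Before the data were examined, 41 gene lists were fixed from textbook knowledge for the cell types of skin, melanocytic cells, growth, immune cells and their signals, and housekeeping groups. Of their 691 genes 602 were tested. Each list was tested with limma's camera (preset inter-gene correlation 0.01, Benjamini-Hochberg over lists), beside camera with an estimated correlation and fry, whose p tests whether a list's genes move on balance one way. After the data were seen, an exact two-sided permutation test of each list's mean score per sample between the groups was added, with Benjamini-Hochberg over lists.

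The rule for named genes was also fixed before the data were examined. It took, per comparison, the 10 largest increases and decreases among changed genes with a mean of at least 6 in the higher group, the up to 4 changed members with the lowest adjusted p of each list called by camera, and 20 fixed markers of melanocytes, keratinocytes, immune cells and cycling cells. For stepwise genes it took the 5 with the largest smaller step in each direction. It allowed fewer names where space was short, in order of size. The rule gave 277 changed gene results, of which the text names 173. Unchanged fixed markers are not named in every comparison. Where each part stops was set after the results were seen. A draft had dropped gene results, mostly ones that lose their call under an alternative, which the rule does not allow. These were put back after the results were seen, with the genes ranked above them and *CTLA4*. The shares of lost calls in the sensitivity text are computed over all 277.

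The 3' to 5' signal difference of the *ACTB* and *GAPDH* control probe sets and the mean of the hybridization controls were compared between groups with exact two-sided permutation tests in Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1, adjusted over the 6 comparisons. Plots were drawn with matplotlib 3.10.9.

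Alternatives fixed beforehand were a shift of each array to the same median, quantile normalization, no filter or a minimum of 6, the probe set with the highest SD, every probe set tested, no fold minimum, array weights, trend and robust variance, the compared groups alone, the 3' to 5' difference as a covariate, other choices of control probe set, other list tests, and each sample left out in turn. Counts were also compared with those of 100 splits of the samples into groups of the same sizes. The procedure was tested on simulated data of these sizes, with 100 genes changed by 1.5 and 100 by 2.5 (log2) per comparison. Of these 87% to 97% and 96% to 100% were called, with 1 to 3 unchanged genes. The shifted list was called in each with 0 of 40 other lists. Other splits called a median of 0 genes (up to 641) and 7 to 15 lists, so this cannot vouch for either.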

Results

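Gene expression was measured on whole-genome oligonucleotide arrays in 34 human skin samples. They comprised 6 samples of normal skin, 5 common melanocytic nevi (benign moles), 7 dysplastic nevi (moles with atypical features) and 16 primary melanomas. The deposited values are log2 probe set summaries normalised by the authors. One probe set was kept for each gene, and 17910 genes were tested. Arrays give no read depth, so their number in each group limits the precision. Per the labels, nevi and normal skin had double amplification and melanomas a standard protocol. Nevi were sliced sections, normal skin bulk biopsies and melanomas whole regions. Titles mark all but melanomas as re-analyzed. Protocol, material or mark thus went with the group in every comparison but that of the nevi, and could not be separated from it. The labels do not state whether each nevus came from a separate donor, and the p-values measure the spread between these samples alone. Differences are given on the log2 scale as the mean of the group named before minus that of the group named after, ± SE, with limma's adjusted p, and a gene was counted as changed at an adjusted p under 0.05 and at least a 2-fold difference. A list score is the mean log2 value of a list's genes in a sample. The array controls set 4 nevi apart, common nevus replicates 4 and 5 and dysplastic nevus replicates 6 and 7, called nevi of high control signal below. Their hybridization control signal was 11.11 to 11.45 and their 3' to 5' difference 3.11 to 4.37, against 10.00 to 10.84 and 2.5 to 2.96 in the 8 others. Their titles also have higher numbers than the others', apart from common nevus replicates 1 and 2, titled by another scheme. The labels explain none of this, and the fits that use it were chosen after seeing the data.

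Dysplastic nevi (n = 7) were compared with common nevi (n = 5), the opening step of the progression named in the series title. Of 17910 genes, 1 was higher and 2 were lower in dysplastic nevi. *ZSWIM3*, which encodes a zinc finger protein with a SWIM domain, was 2.11-fold higher (6.98 ± 0.34 against 5.91 ± 0.19, SD, adjusted p = 0.00374), with 7 of 7 dysplastic nevi above every common nevus. The long noncoding RNA *C2orf49-DT* was 2.21-fold lower (4.89 ± 0.22 against 6.04 ± 0.37, adjusted p = 0.00126), again in 7 of 7. *INTS7*, a subunit of the Integrator complex that processes small nuclear RNAs, was 2.96-fold lower (5.89 ± 0.74 against 7.45 ± 0.44, adjusted p = 0.0465), in 6 of 7. At an unadjusted p under 0.05 there were 924 higher and 823 lower genes, where 896 in all would arise by chance.

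The melanocyte lineage list was level between the nevi, at 9.68 ± 0.45 (SD) in dysplastic and 9.69 ± 0.33 in common nevi (camera adjusted p = 0.951), although its mean and median differences, of -0.01 and 0.02, differed in sign. Its members *MLANA* and *PMEL* differed by -0.50 ± 0.97 (adjusted p = 0.906) and 1.23 ± 0.82 (adjusted p = 0.66). None of the lists below held a gene that passed the test over all genes. The fibroblast and collagen matrix list was higher by 0.84 ± 0.27 (camera adjusted p = 8.71e-14; 0.604 with estimated correlation, 0.202 with fry and 0.104 by permutation, so not called by these), with 0 of its 18 measured members changed over all genes and 6 when adjusted over the list alone. Larger mean differences came from the hair follicle list (1.95 ± 0.62, camera adjusted p = 0.000126, permutation adjusted p = 0.146) and the activated keratinocyte list (1.77 ± 0.64, camera adjusted p = 1.35e-06, permutation adjusted p = 0.129), each with adjusted p = 0.604 with estimated correlation. Within the activated keratinocyte list, *S100A8*, a subunit of the inflammatory protein calprotectin, differed by 1.93 ± 0.89 (adjusted p = 0.474). The macrophage and monocyte list was higher by 0.67 ± 0.27 (camera adjusted p = 6.93e-08; 0.604 with estimated correlation, 0.376 with fry and 0.173 by permutation), and its scavenger receptor gene *CD163* by 0.86 ± 0.42 (adjusted p = 0.503). Among single immune genes, the T cell genes *CD3D* and *CD8A* differed by 0.11 ± 0.39 and 0.39 ± 0.43, the T cell attracting chemokines *CXCL9* and *CXCL10* by -0.91 ± 0.89 and -0.46 ± 0.80, and the immunosuppressive genes *CD274* (PD-L1) and *IDO1* by 0.20 ± 0.42 and 0.39 ± 0.57, with adjusted p between 0.78 and 0.954. *PRAME*, *MKI67*, *KRT10* and *KRT14* differed by 0.17 ± 0.90, 0.45 ± 0.34, 0.27 ± 0.20 and 0.35 ± 0.29 (adjusted p between 0.698 and 0.971).

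With the preset correlation, camera called 17 of 41 lists higher and 2 lower in dysplastic nevi. With an estimated correlation it called 0 (lowest adjusted p = 0.604, 2 at an unadjusted p under 0.05), limma's fry called 0 (4 unadjusted), and an exact permutation test of the list scores, chosen after seeing the data, called 0 (lowest adjusted p = 0.104, 11 unadjusted). Without common nevus replicate 1 or dysplastic nevus replicate 5, camera called 10 and 12 lists. The count of higher genes was 4 without common nevus replicate 1, 18 without common nevus replicate 3 and 3 without dysplastic nevus replicate 6, while in a fit of the nevi alone 0 genes were higher and 0 lower (adjusted p of these 3 genes between 0.116 and 0.303). *INTS7* lost its call without common nevus replicate 2, 4 or 5 or dysplastic nevus replicate 1, 2, 3, 6 or 7 (adjusted p between 0.0627 and 0.153), and with every probe set tested (0.0575), array weights (0.204) or the covariate (0.0598).

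These differences were also computed within the sets of nevi. The fibroblast difference of 0.84 was 0.46 within the 4 nevi of high control signal and 0.96 within the 8 others, and the macrophage difference of 0.67 was 0.33 and 0.74. Among those 8, the set with another title scheme holds common nevi only. Without it, dysplastic nevus replicates 1 to 5 against common nevus replicate 3 differed by 0.32 and 0.23. Over the 2 sets together, with all 12 nevi, the differences were 0.78 (exact p = 0.00595 over the 336 splits within sets, adjusted p = 0.0915) and 0.60 (exact p = 0.0268, adjusted p = 0.122). With that scheme left out they were 0.39 (exact p = 0.0833 over 36 splits) and 0.28 (exact p = 0.25). With the nevi of high control signal as a block, 2 genes were higher and 3 lower, *ZSWIM3*, *C2orf49-DT* and *INTS7* kept their calls (adjusted p = 0.00297, 0.002 and 0.0468) and camera called 18 lists. Without these nevi 0 genes were higher and 0 lower. *ZSWIM3* and *C2orf49-DT* then differed by 0.91 and -1.02 (adjusted p = 0.153 and 0.0738), *INTS7* kept 0.639 of its difference (adjusted p = 0.357), and camera called 16 lists. Of the 210 ways to leave out 2 nevi of each group, 41 left 0 genes. With the block and without the common nevi of another title scheme, 4 genes were higher and 0 lower, *ZSWIM3* kept its call (1.34, adjusted p = 0.00394) and the others did not (adjusted p = 0.0665 and 0.0819). Camera then called 4 lists. With 1 common nevus left in its set, list differences between the groups of nevi could not be told from differences between title schemes.

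**Figure D1:**
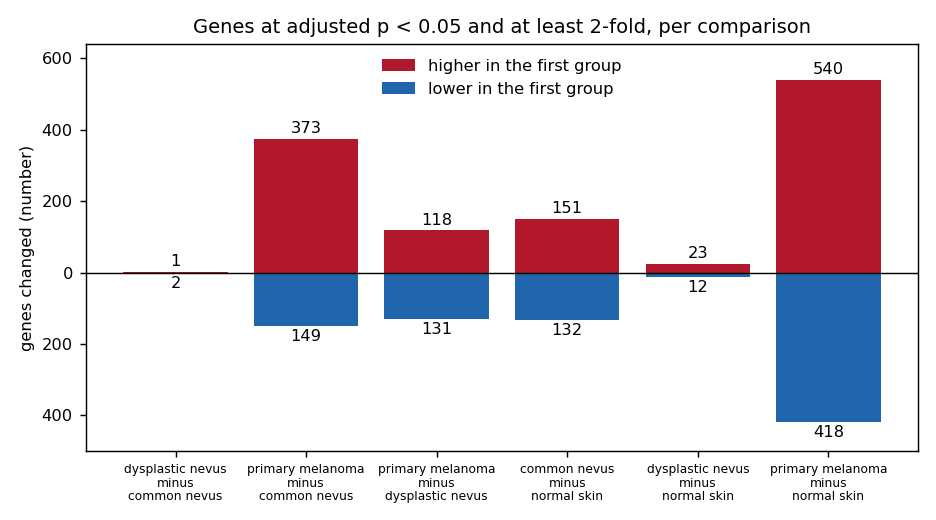
Bars show the number of genes at an adjusted p under 0.05 and at least a 2-fold difference in each comparison, upward for genes higher and downward for genes lower in the group named before "minus".

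Primary melanomas (n = 16) were compared with common nevi (n = 5). Melanomas had 373 genes higher and 149 lower. Macrophage genes stood out: 14 of 19 measured members of the macrophage and monocyte list rose, and its score was above every common nevus in 16 of 16 melanomas (8.35 ± 0.48 against 6.81 ± 0.39, SD). *C1QA*, a chain of the complement component C1q made by macrophages, was 5.85-fold higher (8.88 ± 0.61 against 6.33 ± 0.45), and the checkpoint receptor gene *HAVCR2* (TIM-3) 3.84-fold higher (7.35 ± 0.48 against 5.41 ± 0.53), each above every common nevus in 16 of 16. The melanocyte lineage means were equal (9.69 ± 1.20 against 9.69 ± 0.33, camera adjusted p = 0.914), with 2 melanomas (7.25 and 7.14) below all normal skin.

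The largest increases included the serpin *SERPINB4* (3.86 ± 1.07) and the calprotectin subunits *S100A9* (3.80 ± 0.72) and *S100A8* (2.86 ± 0.77). The matrix protein osteopontin *SPP1* (3.34 ± 0.95), the collagenase *MMP1* (3.25 ± 0.95), the protease inhibitor elafin *PI3* (3.11 ± 0.76) and the monocyte attracting chemokine *CCL8* (2.99 ± 0.47) were also among them. So were the tumour antigen *PRAME* (2.97 ± 0.79, above every common nevus in 12 of 16) and the metalloprotease-like gene *ADAMDEC1* (2.96 ± 0.76). The adjusted p of these genes lay between 0.000131 and 0.022. The growth factor gene *EGFL6* was last in size (2.79 ± 0.92, adjusted p = 0.0414). The largest decreases were in *HKDC1*, a hexokinase domain gene (-3.30 ± 0.51), *GRIA1*, a glutamate receptor subunit (-3.21 ± 0.47), *HHATL* (-3.21 ± 0.97), *PTN*, the growth factor pleiotrophin (-3.21 ± 0.49), and the transcription factor *TFAP2B* (-2.53 ± 0.55), with adjusted p between 6.14e-05 and 0.0255.

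The 14 macrophage and monocyte genes (15 adjusted over the list alone) included *C1QA* (2.55 ± 0.31), *C1QC* (2.29 ± 0.35), the endotoxin co-receptor *CD14* (1.87 ± 0.31) and *CD163* (2.09 ± 0.36), with adjusted p between 1.53e-05 and 0.000367 (list score 1.54 ± 0.21, adjusted p = 2.78e-17 by camera and 0.00201 by permutation). Of 14 complement genes 10 rose (10 over the list alone), among them the C3a receptor *C3AR1* (1.63 ± 0.25), the C3b protease *CFI* (1.26 ± 0.25), the C5a receptor *C5AR1* (1.27 ± 0.26) and *C2* (1.29 ± 0.28; list score 1.04 ± 0.20, adjusted p = 4.26e-08 by camera and 0.00201 by permutation). Both lists lost their call with estimated correlation (adjusted p = 0.216 each). In the cytotoxic T and NK cell list, 6 of 18 genes rose (6 over the list alone), including the granzyme *GZMK* (2.53 ± 0.45) and the transcription factor *EOMES* (1.85 ± 0.35; list score 0.99 ± 0.21, adjusted p = 3.01e-07 by camera and 0.018 by permutation). Of 18 T cell genes 6 rose (8 over the list alone). They included the receptors *CD28* (1.93 ± 0.42, from 3.78, under the minimum of 4) and *CD27* (1.62 ± 0.38). The score rose 0.92 ± 0.20 (adjusted p = 3.93e-07 by camera and 0.0242 by permutation). *CD8A* and *CD3D* differed by 1.13 ± 0.38 and 0.66 ± 0.34 (adjusted p = 0.0423 and 0.206). Estimated correlation gave both lists adjusted p = 0.302.

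Of 35 checkpoint and negative regulation genes, which restrain immune responses, 6 rose (7 over the list alone; list score 0.56 ± 0.09, adjusted p = 1.51e-06 by camera and 0.00363 by permutation), with adjusted p = 0.26 with estimated correlation. *HAVCR2* (1.94 ± 0.22, adjusted p = 5.86e-06), the inhibitory receptor *LAIR1* (1.47 ± 0.22), the cytokine signalling suppressor *SOCS3* (2.48 ± 0.43) and the interleukin 10 receptor *IL10RA* (1.40 ± 0.28) had the lowest p. *CD274* rose by 1.27 ± 0.37 (adjusted p = 0.0211). Of 20 type 1 (interferon gamma) axis genes 6 rose (10 over the list alone), including the chemokine *CCL4* (1.80 ± 0.31) and the interferon regulatory factor *IRF1* (1.30 ± 0.23; list score 0.93 ± 0.22, adjusted p = 1.49e-05 by camera and 0.0357 by permutation, with adjusted p = 0.304 with estimated correlation). *CXCL9* (1.98 ± 0.77, adjusted p = 0.0857), *CXCL10* (1.92 ± 0.70, adjusted p = 0.0641) and *IDO1* (1.44 ± 0.50, adjusted p = 0.0538) did not pass. In the type I interferon response list 5 of 27 rose (7 over the list alone), including *IFI27* (1.91 ± 0.42) and *SAMD9L* (1.73 ± 0.42; list score 0.89 ± 0.19, adjusted p = 5.7e-08 by camera and 0.0366 by permutation, with adjusted p = 0.302 with estimated correlation).

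Outside the immune lists, 9 of 25 invasion and matrix remodelling genes rose (9 over the list alone; list score 0.73 ± 0.12, adjusted p = 0.00219 by camera and 0.00529 by permutation). They included the urokinase *PLAU* (1.83 ± 0.27) and its receptor *PLAUR* (1.32 ± 0.25). The fibroblast and collagen matrix list had 6 of 18 genes higher (6 over the list alone; list score 0.92 ± 0.26, adjusted p = 4.26e-08 by camera and 0.0137 by permutation), among them *COL6A3* (1.13 ± 0.23) and *THY1* (1.16 ± 0.26). Of 13 activated keratinocyte genes 5 rose (9 over the list alone; list score 2.35 ± 0.59, adjusted p = 4.29e-06 by camera and 0.0232 by permutation). These 3 lists had an adjusted p between 0.26 and 0.302 with estimated correlation. In the proliferation list 2 of 26 rose, the mitotic kinase *AURKA* (1.69 ± 0.45) and the spindle factor *TPX2* (1.42 ± 0.34). *MKI67* differed by 0.65 ± 0.30 (adjusted p = 0.147). That list passed camera (adjusted p = 0.00139) and not the permutation test (adjusted p = 0.184) or an estimated correlation (adjusted p = 0.522). *MLANA* (-0.97 ± 0.85), *PMEL* (1.65 ± 0.72), *KRT10* (-0.10 ± 0.17) and *KRT14* (-0.12 ± 0.25) did not pass (adjusted p between 0.126 and 0.803).

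Camera called 24 of 41 lists in this comparison, fry 22 and the permutation test of list scores 17, of which 16 were also called by camera, while an estimated correlation left 0 (lowest adjusted p = 0.216, 6 at an unadjusted p under 0.05). Calls were lost for *SPP1* without common nevus replicate 4 (adjusted p = 0.0542), for *MMP1* (0.0575) and *S100A8* (0.0766) without replicate 2, for *HHATL* without replicate 2 (0.128) or 5 (0.0617), and for *CD274* without replicate 3 (0.073) or 4 (0.103). The difference of *COL6A3* was 0.94, under 2-fold, without common nevus replicate 5, and *CD8A* lost its call without common nevus replicate 1, 2, 3 or 5 or melanoma replicate 2, 4, 5, 9, 11 or 15 (adjusted p up to 0.105). Passing values came for *CXCL9* without common nevus replicate 4 or melanoma replicate 8 or 16 (adjusted p between 0.0432 and 0.0463), for *CXCL10* without melanoma replicate 16 (0.0358), for *PMEL* without melanoma replicate 8 (0.0341) or 9 (0.0266), and for *IDO1* without melanoma replicate 5, 8, 10, 12, 13, 14 or 16 (between 0.0298 and 0.0493). With the 3' to 5' difference as a covariate *CXCL9* (2.54, adjusted p = 0.0214), *CXCL10* (2.23, 0.0361) and *IDO1* (1.76, 0.0177) passed, as did *IDO1* with a minimum of 6 (0.0417) and without the melanomas of low melanocyte score (0.0419). In a fit of these groups alone, *PRAME*, *MMP1*, *HHATL*, *CD274* and *CD8A* did not pass (adjusted p between 0.0526 and 0.09), and with array weights *SPP1* (0.0687), *CD274* and *CD8A* (0.0829 each) did not. *HHATL* did not pass with the covariate (0.0523), nor *CD8A* without the melanomas of low melanocyte score (0.0523). *EGFL6* lost its call in 11 of the 21 fits that left out 1 sample (adjusted p up to 0.122), in a fit of these groups alone (0.0674) and with the 3' to 5' difference as a covariate (0.0574), and without the melanomas of low melanocyte score (0.065). The checkpoint receptor *CTLA4*, measured by a probe set that hardly varied, differed by -0.01 ± 0.11 (adjusted p = 0.971). With the probe set of highest SD it was 1.84 higher in melanomas (adjusted p = 0.0101), so its call depends on the probe set.

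With the nevi of high control signal as a block, melanomas had 257 genes higher and 151 lower than common nevi, and without them 268 and 193. *CD274*, *CD8A*, *EGFL6*, *GDF15*, *MMP1* and *SPP1* passed in neither fit (adjusted p between 0.0651 and 0.181), with differences close to those with all nevi (*GDF15* 2.57 and 2.66, *CD8A* 1.15 and 1.28, *MMP1* 2.80 and 3.31, *EGFL6* 2.57 and 2.56), and *COL6A3* was under 2-fold in both (0.79 and 0.99). *HHATL* did not pass with the block (adjusted p = 0.0996). *AURKA*, *CXCL8*, *PI3*, *PRAME*, *SAMD9L*, *SERPINB4* and *TPX2* did not pass without these nevi (adjusted p between 0.0506 and 0.107). Over the 522 changed genes the median share of the difference kept was 0.941 with the block and 0.989 without these nevi. Camera called 23 lists with the block and 20 without these nevi. The permutation test without them called 10, the macrophage (1.39), complement, checkpoint and cytotoxic lists among them (adjusted p = 0.0423 each), while the T cell and activated keratinocyte (0.0635 each), type 1 axis (0.0705), fibroblast (0.0767) and type I interferon lists (0.0891) did not pass.

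**Figure D2:**
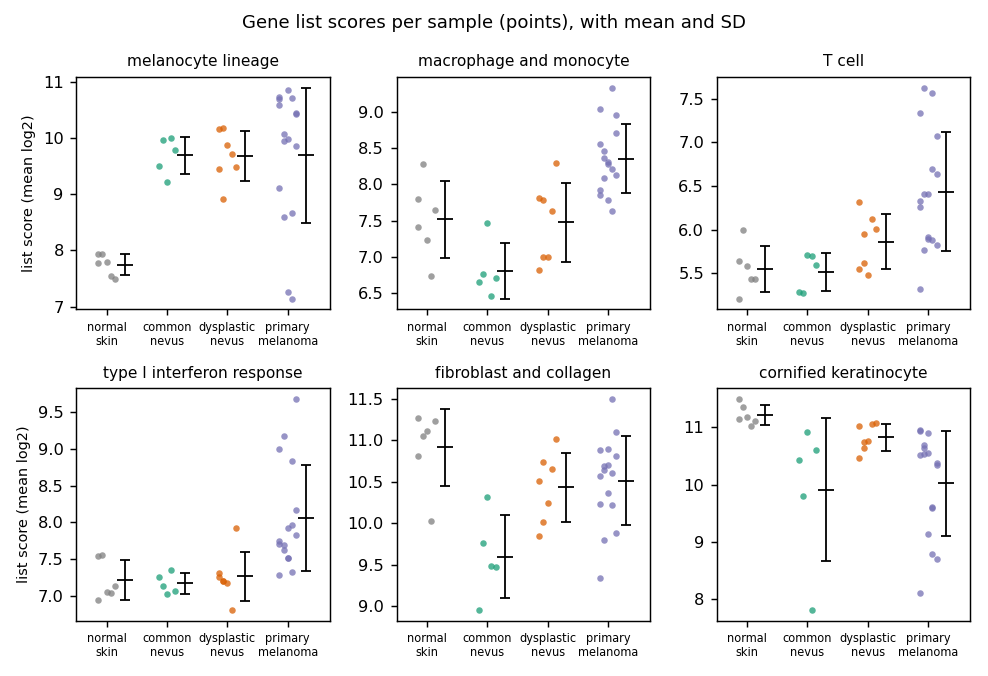
Points show each sample's score for 6 gene lists (mean log2 value of the list's genes) in the 4 groups, with the group mean (bar) and SD (whiskers).

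Primary melanomas (n = 16) were then compared with dysplastic nevi (n = 7), the closing step of the progression. Melanomas had 118 genes higher and 131 lower. *CXCL9* was 7.41-fold higher (9.05 ± 1.87 against 6.16 ± 0.68, SD), above every dysplastic nevus in 14 of 16 melanomas, and *C1QA* 3.48-fold higher (8.88 ± 0.61 against 7.07 ± 0.63), in 16 of 16. *LAMB4*, a laminin chain, was 6.04-fold lower (4.73 ± 0.96 against 7.33 ± 0.56), in 16 of 16.

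After *CXCL9* (2.89 ± 0.69), the largest increases were in *PRAME* (2.80 ± 0.70), the long noncoding RNA *LINC00518* (2.76 ± 0.79), *CCL8* (2.41 ± 0.41), *CXCL10* (2.37 ± 0.62) and the transporter *ABCB5* (2.37 ± 0.58), with adjusted p between 0.00135 and 0.0291. Decreases were largest in *LAMB4* (-2.59 ± 0.34, adjusted p = 9.08e-05) and *CCL27*, a keratinocyte chemokine that attracts skin-homing T cells (-2.49 ± 0.47, adjusted p = 0.00232). The secretoglobin *SCGB1D2* (-2.49 ± 0.79, adjusted p = 0.0474), the secreted gland protein *CRISP3* (-2.35 ± 0.64, adjusted p = 0.0226) and haemoglobin *HBB* (-2.21 ± 0.70, adjusted p = 0.0481) followed. Of 19 macrophage and monocyte genes 8 rose (8 over the list alone; list score 0.88 ± 0.24, adjusted p = 7.46e-09 by camera and 0.0166 by permutation). Among them were *C1QA* (1.80 ± 0.27), the scavenger receptor *MSR1* (1.29 ± 0.25), the Fc receptor *FCGR2A* (1.38 ± 0.28) and *C1QB* (1.74 ± 0.39). *CD163* rose by 1.23 ± 0.32 (adjusted p = 0.0173). Of 20 type 1 axis genes 7 rose (9 over the list alone; list score 0.94 ± 0.19, adjusted p = 3.26e-07 by camera and 0.0241 by permutation). They included *CCL4* (1.49 ± 0.28) and the guanylate binding protein *GBP5* (1.45 ± 0.32). *IDO1* did not pass (1.05 ± 0.44, adjusted p = 0.142). The cytotoxic T and NK cell list had 6 of 18 higher (7 over the list alone; list score 0.79 ± 0.20, adjusted p = 3.26e-07 by camera and 0.0304 by permutation), with *EOMES* (1.26 ± 0.31) and the granzyme *GZMH* (1.15 ± 0.29) among them. These 3 lists had an adjusted p of 0.303 or 0.316 with estimated correlation.

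Type I interferon response genes rose in 6 of 27 cases (6 over the list alone; list score 0.79 ± 0.22, adjusted p = 1.7e-08 by camera and 0.0367 by permutation), with *IFIT3* (1.19 ± 0.33, adjusted p = 0.0246) having the lowest p and *ISG15* the next (1.25 ± 0.36, adjusted p = 0.0288). In the checkpoint list 3 of 35 rose (4 over the list alone; list score 0.36 ± 0.08, adjusted p = 3.51e-05 by camera and 0.0241 by permutation). Among them were the inhibitory receptor *TIGIT* (1.12 ± 0.28, adjusted p = 0.0141), *SOCS3* (1.35 ± 0.38, adjusted p = 0.0259) and *CD274* (1.07 ± 0.33, adjusted p = 0.0404). The T cell list had 1 of 18 higher, *CD28* (1.61 ± 0.37, adjusted p = 0.00844; 2 over the list alone). It passed camera (adjusted p = 0.000308) and not the permutation test (adjusted p = 0.0936). *CD3D* (0.55 ± 0.30, adjusted p = 0.27) and *CD8A* (0.75 ± 0.33, adjusted p = 0.163) did not pass. With an estimated correlation these lists had adjusted p = 0.316, 0.303 and 0.456.

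Of 10 sweat gland genes 2 fell (7 over the list alone; list score -1.51 ± 0.34, adjusted p = 6.5e-06 by camera and 0.0241 by permutation), including the duct keratin *KRT77* (-1.87 ± 0.38, adjusted p = 0.00345). The Langerhans cell list had 1 of 7 lower (5 over the list alone; list score -1.06 ± 0.25, adjusted p = 2.95e-05 by camera and 0.0241 by permutation), the antigen presenting gene *CD1E* (-1.57 ± 0.44, adjusted p = 0.0277). The basal keratinocyte list had 1 of 8 lower (1 over the list alone; list score -0.46 ± 0.13, adjusted p = 0.00487 by camera and 0.0548 by permutation), *KRT15* (-1.31 ± 0.36, adjusted p = 0.0246). The adjusted p was 0.303 for each of these lists with estimated correlation. *KRT10* (-0.37 ± 0.15), *KRT14* (-0.47 ± 0.23), *S100A8* (0.93 ± 0.69), *MKI67* (0.19 ± 0.26), *MLANA* (-0.47 ± 0.75) and *PMEL* (0.42 ± 0.64) did not pass (adjusted p between 0.132 and 0.757). Camera called 25 lists, fry 14, the permutation test 12, all of them also called by camera, and an estimated correlation 0 (lowest adjusted p = 0.303, 5 unadjusted). Without dysplastic nevus replicate 3 the higher genes numbered 76. Calls were lost for *LINC00518* without dysplastic nevus replicate 1, 2, 3 or 4, for *IFIT3* without 2, 3 or 4, for *CD1E* without 1, 2, 4 or 5, for *CD163* without 3 or 6, for *KRT15* without 6, and for *CD274* without 2, 3, 4, 6 or 7 or melanoma replicate 2, 4, 5, 9, 11, 13 or 15, with adjusted p between 0.0503 and 0.0933. *LINC00518*, *IFIT3*, *KRT15* and *CD274* did not pass in a fit of these groups alone (adjusted p between 0.0597 and 0.0714), and *CD274* was under 2-fold with array weights (0.93). The decreases of *HBB* and *SCGB1D2* lost their calls in 17 and 14 of the 23 fits that left out 1 sample (adjusted p up to 0.0979 and 0.117) and with no filter (0.0533 and 0.0523) or every probe set tested (0.0543 and 0.0536), and *HBB* also with array weights (0.0588). *CRISP3* lost its call without dysplastic nevus replicate 2 (0.0776), *SOCS3* without 4, 5 or 7 (up to 0.0686), and *ISG15* without 3, 4 or 7 (up to 0.0701) or in a fit of these groups alone (0.056).

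Without the nevi of high control signal, 67 genes were higher and 131 lower in melanomas than in dysplastic nevi, and with these nevi as a block 100 and 177. *CD163*, *CD274*, *CXCL8* and *HBB* passed in neither (adjusted p between 0.0505 and 0.153), with differences of 1.03 and 0.92 for *CD163*, 0.92 and 0.83 for *CD274*, 1.33 and 1.32 for *CXCL8*, and -1.92 and -2.02 for *HBB*. *C1QB*, *CD28*, *EOMES*, *ISG15*, *KRT15* and *SOCS3* did not pass without these nevi (adjusted p between 0.0554 and 0.082). Over the 249 changed genes the median share of the difference kept was 1.00 and 0.989. Camera then called 13 lists, and 16 with the block. The permutation test without these nevi called 0 (lowest adjusted p = 0.0907, 15 unadjusted), with the macrophage list higher by 0.65 (adjusted p = 0.0958).

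The series title raises the question of stepwise change in immune genes. By limma's adjusted test 0 genes were stepwise higher and 0 lower (103 and 27 unadjusted). Only 7 genes passed from common to dysplastic nevi, so stepwise change stays open. Macrophage and monocyte scores were 6.81 ± 0.39 (SD) in common nevi, 7.48 ± 0.55 in dysplastic nevi and 8.35 ± 0.48 in melanomas. By permutation the lower step did not pass (0.67 ± 0.27, adjusted p = 0.173) and the upper did (0.88 ± 0.24, 0.0166). Checkpoint scores were 5.87 ± 0.12, 6.07 ± 0.10 and 6.43 ± 0.27. Their steps were 0.19 ± 0.06 and 0.36 ± 0.08 (permutation adjusted p = 0.104 and 0.0241). Neither upper step passed without the nevi of high control signal (adjusted p = 0.0958 each) or with estimated correlation. Type 1 axis scores were 5.90 ± 0.24, 5.88 ± 0.16 and 6.82 ± 0.74, so that the lower step was -0.02 ± 0.12 (permutation adjusted p = 0.911). Without common nevus replicate 3, 1 gene was stepwise higher and 1 lower. With the nevi of high control signal as a block, 1 was stepwise higher.

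**Figure D3:**
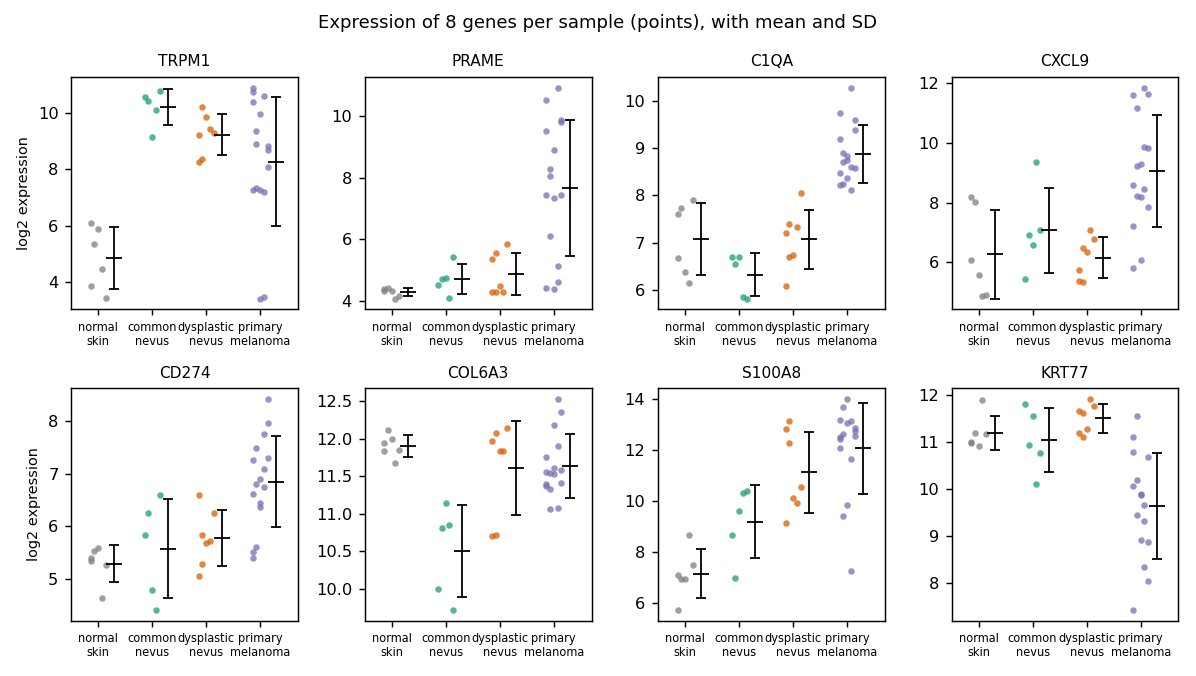
Points show the log2 expression of 8 genes in each sample of the 4 groups, with the group mean (bar) and SD (whiskers).

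Common nevi (n = 5) were compared with normal skin (n = 6), the tissue in which they arise. Common nevi had 151 genes higher and 132 lower. *TRPM1*, the melanocytic cation channel melastatin, was 40.3-fold higher (10.19 ± 0.63 against 4.86 ± 1.10, SD), and the collagen chain *COL6A3* 2.64-fold lower (10.50 ± 0.61 against 11.90 ± 0.15), each beyond every normal skin sample in 5 of 5 nevi.

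The largest increases were in *TRPM1* (5.33 ± 1.00, adjusted p = 0.00586), *HHATL* (4.18 ± 1.14, adjusted p = 0.0358), *MLANA* (4.01 ± 1.01, adjusted p = 0.0249) and *HKDC1* (3.69 ± 0.61, adjusted p = 0.00196). Of 19 melanocyte lineage genes 9 rose (12 over the list alone; list score 1.95 ± 0.17, adjusted p = 4.27e-11 by camera and 0.0296 by permutation). They included the lineage transcription factor *MITF* (1.86 ± 0.36), *S100B* (3.06 ± 0.60) and the endothelin receptor *EDNRB* (2.61 ± 0.55), with adjusted p between 0.00767 and 0.0123. The melanosome gene *PMEL* was 2.83-fold higher and did not pass (adjusted p = 0.327). Next in size were the adhesion gene *IGSF11* (3.65 ± 0.85), the matrix gene *CRTAC1* (3.49 ± 0.78), *GRIA1* (3.49 ± 0.56), the long noncoding RNA *IDI2-AS1* (3.43 ± 0.77) and the melanocyte transcription factor *PAX3* (3.40 ± 0.83), with adjusted p between 0.00167 and 0.0229. Decreases were largest in the copper carrier ceruloplasmin *CP* (-3.07 ± 0.58), the matrix protein gene *CILP* (-2.79 ± 0.65) and the matricellular gene *CCN5* (-2.65 ± 0.46), with adjusted p between 0.00437 and 0.0192. The antimicrobial ribonuclease *RNASE7* (-2.51 ± 0.67, adjusted p = 0.0319) and *PCOLCE2* (-2.47 ± 0.59, adjusted p = 0.0201) came next. In the fibroblast and collagen matrix list 11 of 18 genes fell (13 over the list alone; list score -1.32 ± 0.29, adjusted p = 6.63e-17 by camera and 0.038 by permutation). Among them were the growth factor receptor *PDGFRB* (-1.65 ± 0.32), *COL6A3* (-1.40 ± 0.28) and fibrillin *FBN1* (-1.92 ± 0.41). Of 14 complement genes 4 fell (7 over the list alone; list score -0.84 ± 0.22, adjusted p = 3.74e-06 by camera and 0.0394 by permutation), the regulator *CD55* (-1.49 ± 0.27) and the protease *C1S* (-1.38 ± 0.33) among them. These 3 lists had adjusted p between 0.375 and 0.491 with estimated correlation.

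The cornified keratinocyte list had 1 of 20 genes lower (10 over the list alone; list score -1.30 ± 0.56, adjusted p = 1.45e-08 by camera and 0.0296 by permutation), with adjusted p = 0.562 with estimated correlation. *KRT10* differed by -0.50 ± 0.21 (adjusted p = 0.167). In the list of MAPK pathway output, the growth factor signalling route that nevi commonly activate, 1 of 14 genes rose (5 over the list alone; list score 0.69 ± 0.15, adjusted p = 0.00313 by camera and 0.0296 by permutation), the transcription factor *ETV5* (2.15 ± 0.53, adjusted p = 0.0224), with adjusted p = 0.612 with estimated correlation. *CD163* differed by -0.98 ± 0.43 (adjusted p = 0.197). Camera called 12 lists, fry 5, the permutation test 9, of which 8 were also called by camera, and an estimated correlation 0 (lowest adjusted p = 0.375, 3 unadjusted). The counts were 65 to 100 higher and 55 to 84 lower without common nevus replicate 1, 2 or 4 or normal skin replicate 2, 3, 5 or 6, then 259 and 236 without common nevus replicate 3, and 76 lower without common nevus replicate 5. Calls were lost for *CILP* without common nevus replicate 1 or 4, for *ETV5* without 2 or 4, for *MLANA* without 1, 2, 4 or 5 or normal skin replicate 5, and for *HHATL* without common nevus replicate 1, 2 or 5 or normal skin replicate 2, 3, 5 or 6, with adjusted p between 0.0505 and 0.109. *HHATL* also lost it with the covariate (0.059).

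In the invasion and matrix remodelling list, common nevi had more of the protease inhibitor *SERPINE2* (3.01 ± 0.66). They had less of the gelatinase *MMP2* (-1.97 ± 0.44), the receptor kinase *AXL* (-1.38 ± 0.31) and fibronectin *FN1* (-1.56 ± 0.40), with adjusted p between 0.0154 and 0.0261. The collagen chain *COL6A2* fell by 1.75 ± 0.40 (adjusted p = 0.0173) and the sebaceous gland gene *FAR2* rose by 3.05 ± 0.72 (adjusted p = 0.0197). *MMP2*, *AXL* and *COL6A2* lost their calls without common nevus replicate 1, *PCOLCE2* without 4, *PAX3* without 1 or 2, *FAR2* without 1 or 4, and *C1S* without 1, 4 or 5 (adjusted p between 0.0505 and 0.0717). *FN1* lost its call in 6 of the 11 fits that left out 1 sample (adjusted p up to 0.087), and with the probe set of highest SD (adjusted p = 0.248). *RNASE7* lost its call in 9 of the 11 (adjusted p up to 0.105), and with the 3' to 5' difference as a covariate (0.0523).

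With the nevi of high control signal as a block, 10 genes were higher and 8 lower in common nevi than in normal skin, and without them, with 3 common nevi left, 28 and 20. The differences themselves stayed: over the 283 changed genes the median share kept was 0.883 and 0.932, all in the same direction. Without these nevi *TRPM1* differed by 5.18, *HHATL* by 4.89 and *MLANA* by 3.64. In 210 ways to leave out 2 nevi of each group the median was 33 changed genes against 48 here. Of them 115 gave as few, so the loss is no larger than with other nevi left out. With such sets as the block the median was 162 against 18 here, and 9 of 210 gave as few. Of the 29 changed gene results named for this comparison, 5 passed with the block (*TRPM1*, *HKDC1*, *GRIA1*, *CCN5* and *CD55*; the others had adjusted p between 0.0527 and 0.164). Without these nevi 7 passed (*HKDC1*, *GRIA1*, *S100B*, *CP*, *CCN5*, *PDGFRB* and *COL6A3*; the others had adjusted p between 0.0517 and 0.212). Camera called 11 and 12 lists. The permutation test without these nevi called 0 (lowest adjusted p = 0.122, 9 unadjusted), with melanocyte and fibroblast lists differing by 1.81 and -1.24. Its 84 splits allow no p under 0.0119, that of the melanocyte list.

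Dysplastic nevi (n = 7) had 23 genes higher and 12 lower than normal skin (n = 6). *TRPM1* was 20.6-fold higher (9.22 ± 0.72 against 4.86 ± 1.10, SD) and *S100A8* 15.7-fold higher (11.12 ± 1.58 against 7.15 ± 0.95), each above every normal skin sample in 7 of 7. Other increases were in *DNAI3*, a subunit of the dynein motor of cilia (3.35 ± 0.71), and in the melanocyte genes *GPR143* (2.91 ± 0.67) and *MITF* (1.45 ± 0.33), and decreases in *PCOLCE2*, an enhancer of collagen processing (-2.50 ± 0.54), and the tight junction gene *CLDN11* (-1.86 ± 0.39), with adjusted p of 0.0314 or 0.0435. *IDI2-AS1* rose by 3.11 ± 0.71 and the prostacyclin synthase *PTGIS* differed by -1.66 ± 0.38 (adjusted p = 0.0406 each). Of 19 melanocyte lineage genes 3 rose (15 over the list alone; list score 1.94 ± 0.19, adjusted p = 1.89e-18 by camera and 0.0119 by permutation). *MLANA* (3.51 ± 0.93, adjusted p = 0.0896) and *PMEL* (2.73 ± 0.78, adjusted p = 0.124) lay above every normal skin sample in 7 of 7 without passing the test over all genes, though they passed in a fit of these groups alone (adjusted p = 0.00064 and 3.83e-05) and with array weights (0.0172 and 0.0244). In the activated keratinocyte list 1 of 13 rose, *S100A8* (3.98 ± 0.84; 9 over the list alone; list score 2.13 ± 0.52, adjusted p = 9.61e-08 by camera and 0.0358 by permutation). In the MAPK output list 1 of 14 rose, *ETV5* (2.22 ± 0.48; 3 over the list alone; list score 0.62 ± 0.13, adjusted p = 0.000356 by camera and 0.0239 by permutation). With an estimated correlation these lists had adjusted p = 0.308, 0.693 and 0.731. *CD163* differed by -0.12 ± 0.40 (adjusted p = 0.935) and *KRT10* by -0.23 ± 0.19 (adjusted p = 0.668).

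For dysplastic nevi against normal skin, camera called 11 lists, fry 1, the permutation test 4, of which 3 were also called by camera, and an estimated correlation 0 (lowest adjusted p = 0.308, 2 unadjusted). Higher genes numbered 3 or 4 without dysplastic nevus replicate 3, 4, 6 or 7 or normal skin replicate 3, 5 or 6, then 12 and 15 without normal skin replicate 2 and 4, and 39 without dysplastic nevus replicate 5, while lower genes numbered 2 to 7 without dysplastic nevus replicate 2, 3, 4, 6 or 7 or normal skin replicate 1, 3, 5 or 6. *TRPM1*, *S100A8*, *DNAI3*, *GPR143*, *MITF*, *ETV5*, *PCOLCE2*, *CLDN11*, *IDI2-AS1* and *PTGIS* lost their calls in 6 to 11 of the 13 fits that left out 1 sample (adjusted p up to 0.116), always with the same direction. *MITF* and *GPR143* also lost theirs with no filter (0.0513 and 0.0518), and *MITF* and *ETV5* with the probe set of highest SD (0.0529 and 0.075). In a fit of these groups alone there were 154 higher and 47 lower genes. With the nevi of high control signal as a block 7 genes were higher and 6 lower, and without these nevi 0 and 1. None of the 10 changed gene results named for this comparison passed in either fit (adjusted p between 0.0904 and 0.278), with similar differences (*S100A8* 3.72 and 3.98, *TRPM1* 4.21 and 4.17, *DNAI3* 3.19 and 3.18, *GPR143* 2.70 and 2.68). Of the 210 choices of 2 nevi of each group, 102 as the block and 15 left out gave as few changed genes. Camera called 10 and 13 lists, and the permutation test without these nevi 4, among them the melanocyte (1.74) and activated keratinocyte (2.23) lists (adjusted p = 0.0296 each) and not the MAPK output list (0.0532).

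Primary melanomas (n = 16) differed from normal skin (n = 6) in 540 higher and 418 lower genes, the most of the 6 comparisons. *S100A8* was 30-fold higher (12.05 ± 1.77 against 7.15 ± 0.95, SD), above every normal skin sample in 15 of 16. *LINC00518* (4.59 ± 0.83), the psoriasin *S100A7* (4.47 ± 1.10), *S100A9* (4.30 ± 0.67) and *SERPINB4* (3.85 ± 1.00) had the next largest increases, with adjusted p between 4.81e-05 and 0.0055. *TRPM1* (3.41 ± 0.79, adjusted p = 0.00223) and *PRAME* (3.40 ± 0.74, adjusted p = 0.00129) followed. Decreases were largest in the Wnt inhibitor *WIF1* (-3.35 ± 0.62), *LAMB4* (-3.22 ± 0.36), the epidermal growth factor receptor ligand betacellulin *BTC* (-3.21 ± 0.62) and the adhesion receptor *ADGRF4* (-3.13 ± 0.45), with adjusted p between 1.01e-06 and 0.000463. *SCGB1D2* came next (-2.67 ± 0.83, adjusted p = 0.0181), and lost its call without normal skin replicate 3 or 4 (adjusted p = 0.0592 at most).

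Of 19 melanocyte lineage genes 15 rose (15 over the list alone; list score 1.95 ± 0.31, adjusted p = 2.23e-08 by camera and 0.00888 by permutation). They included *EDNRB* (2.11 ± 0.43), *S100B* (2.48 ± 0.47), *GPR143* (3.08 ± 0.58), the transporter *SLC45A2* (2.87 ± 0.57), *MLANA* (3.04 ± 0.80) and *PMEL* (3.15 ± 0.67). Of 20 cornified keratinocyte genes 10 fell (11 over the list alone; list score -1.20 ± 0.24, adjusted p = 7.03e-07 by camera and 0.0192 by permutation). Among them were the desmosomal cadherins *DSC1* (-2.30 ± 0.50) and *DSG1* (-1.67 ± 0.34), filaggrin 2 *FLG2* (-1.67 ± 0.44) and *LCE2B* (-2.61 ± 0.65). *KRT10* was lower by less than 2-fold (-0.60 ± 0.16, adjusted p = 0.00759) and *KRT14* did not pass (-0.53 ± 0.24, adjusted p = 0.103). In the activated keratinocyte list 10 of 13 rose (10 over the list alone; list score 2.72 ± 0.47, adjusted p = 1.63e-05 by camera and 0.00888 by permutation), with *S100A12* (2.30 ± 0.54) among them. Sweat gland genes fell in 5 of 10 cases (6 over the list alone; list score -1.52 ± 0.41, adjusted p = 0.00065 by camera and 0.0192 by permutation), including *KRT77* (-1.56 ± 0.40). The Langerhans cell list had 4 of 7 lower (4 over the list alone), including *FCGBP* (-1.20 ± 0.32), *EPCAM* (-1.32 ± 0.42) and the lectin langerin *CD207* (-1.36 ± 0.44). That list passed camera (adjusted p = 0.0164) and not the permutation test (adjusted p = 0.0657). Among cycling genes 6 of 26 rose (7 over the list alone), including thymidylate synthase *TYMS* (1.72 ± 0.38) and *AURKA* (1.83 ± 0.42), with camera adjusted p = 0.000149 and permutation adjusted p = 0.053, and *MKI67* rose by less than 2-fold (0.78 ± 0.28, adjusted p = 0.0382). Of 14 MAPK output genes 4 rose (4 over the list alone; list score 0.62 ± 0.17, adjusted p = 0.0102 by camera and 0.0379 by permutation), including *FOSL1* (1.26 ± 0.26) and the phosphatase *DUSP6* (1.01 ± 0.24). The proliferation list had adjusted p = 0.542 and the other lists of this paragraph 0.462 with estimated correlation.

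Macrophage and monocyte genes rose in 7 of 19 cases against normal skin (8 over the list alone; list score 0.83 ± 0.25, adjusted p = 6.54e-05 by camera and 0.0102 by permutation). They included *C1QA* (1.79 ± 0.29) and *FCGR2A* (1.49 ± 0.29). *CD163* rose by 1.11 ± 0.34 (adjusted p = 0.0169). Of 20 type 1 axis genes 10 rose (11 over the list alone; list score 1.04 ± 0.23, adjusted p = 3.4e-05 by camera and 0.018 by permutation). Among them were *CCL4* (1.88 ± 0.29), *CXCL10* (2.77 ± 0.65), *CXCL9* (2.78 ± 0.72) and *IDO1* (1.58 ± 0.47). The type I interferon list had 8 of 27 higher (10 over the list alone; list score 0.85 ± 0.21, adjusted p = 1.54e-05 by camera and 0.0304 by permutation), with *IFI27* (1.88 ± 0.39) having the lowest p and *LY6E* (1.06 ± 0.23) the next. In the T cell list 9 of 18 rose (9 over the list alone; list score 0.88 ± 0.20, adjusted p = 3.4e-05 by camera and 0.0201 by permutation), among them *CD3D* (1.10 ± 0.32). In the cytotoxic list 5 of 18 rose (5 over the list alone; list score 0.91 ± 0.22, adjusted p = 6.54e-05 by camera and 0.0192 by permutation), among them *EOMES* (1.70 ± 0.33), *GZMK* (2.14 ± 0.42) and *GZMA* (1.97 ± 0.40). *CD8A* did not pass (0.90 ± 0.35, adjusted p = 0.0586). Of 35 checkpoint genes 5 rose (5 over the list alone; list score 0.42 ± 0.08, adjusted p = 0.0023 by camera and 0.0115 by permutation). They included *CD200* (1.88 ± 0.30) and *CD274* (1.56 ± 0.35). With an estimated correlation each of these 6 lists had adjusted p = 0.462. Camera called 23 lists, fry 23, the permutation test 18, of which 15 were also called by camera, and an estimated correlation 0 (lowest adjusted p = 0.462, 1 unadjusted). *CD163* lost its call without normal skin replicate 4 (adjusted p = 0.0626) or melanoma replicate 9 (difference 0.99, under 2-fold), *CD3D* without melanoma replicate 2 (0.99), and *CD8A* passed without normal skin replicate 2 (adjusted p = 0.0307). *EPCAM* lost its call without normal skin replicate 2 or 4 and *CD207* without 3 (adjusted p up to 0.0622). *DUSP6* and *LY6E* came under 2-fold in 8 and 3 of the 22 fits that left out 1 sample (down to 0.92 and 0.97) and with array weights (0.91 and 0.96), and *DUSP6* also with quantile normalization (0.97). *CTLA4* differed by 0.11 ± 0.10 (adjusted p = 0.472), and by 2.02 with the probe set of highest SD (adjusted p = 0.00141).

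By the number of lists called by camera with the preset correlation, chance was not excluded in any of the 6 comparisons: between 6 and 23 of 100 splits of the same samples, the real one included, called as many. For dysplastic against common nevi, with the block chosen after seeing the data, 2 of 100 splits within the sets of nevi did. The permutation test called the macrophage, type 1 axis, type I interferon, cytotoxic and checkpoint lists higher in all 3 melanoma comparisons, though without the nevi of high control signal it called 3 of them against common nevi (macrophage, cytotoxic and checkpoint) and 0 against dysplastic nevi. The mean, the median and the test had the same sign in every list that camera called. Control probe sets on the arrays gave a measure of the labelling. The mean difference between 3' and 5' probe sets of *ACTB* and *GAPDH*, which grows with shorter or more degraded labelled RNA, was 2.84 ± 0.30 (SD) in dysplastic nevi, 3.23 ± 0.73 in common nevi, 2.91 ± 0.36 in melanomas and 2.98 ± 0.18 in normal skin. No pair of groups differed (permutation adjusted p of 0.662 or 0.663, smallest unadjusted 0.189). The hybridization controls, bacterial transcripts added to each sample after labelling, averaged 9.92 ± 0.37 in melanomas, 10.7 ± 0.65 in common nevi, 10.6 ± 0.47 in dysplastic nevi and 10.5 ± 0.30 in normal skin. Melanomas differed from common nevi, dysplastic nevi and normal skin by -0.81, -0.72 and -0.60 (permutation adjusted p = 0.00688, 0.00631 and 0.00688), and the other 3 groups did not differ (adjusted p between 0.741 and 0.755). Melanoma replicate 10 stood apart at 11.08, against 9.65 to 10.27 in the other 15. Without it the differences were -0.89, -0.80 and -0.68 (exact p = 0.000903, 1.17e-05 and 9.21e-05). Every melanoma comparison above therefore went together with this difference in control signal.

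**Figure D4:**
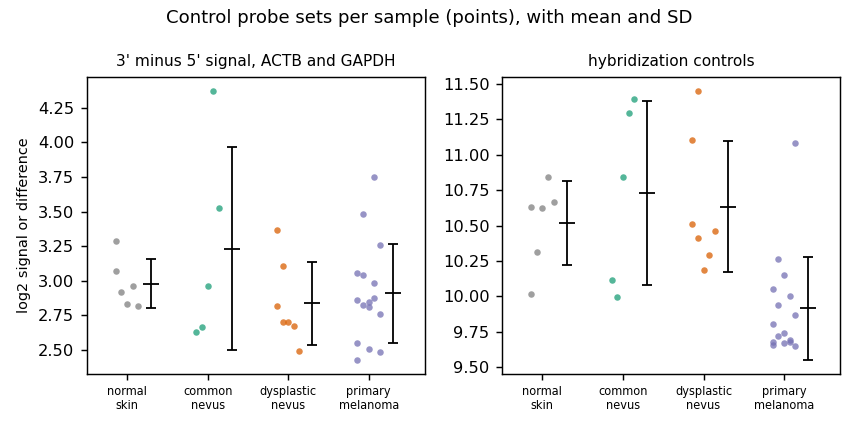
Points show, for each sample of the 4 groups, the 3' minus 5' signal difference of *ACTB* and *GAPDH* (left, log2) and the mean signal of the hybridization controls (right, log2), with group mean (bar) and SD (whiskers).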

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

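The counts over other splits of the samples, and the runs that left out single nevi, were planned before their results were seen; the tests of the macrophage and fibroblast patterns and of the nevi of high control signal were chosen after those results were seen.

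For 308 values of named genes and lists in groups of 5 to 7 samples, the gap between the highest or lowest sample and its neighbour was compared with the range of the group. The gap was unusually large in 25 of them, where about 1 in 20 would be by chance. In common nevi this held for *CD28* (highest, gap 0.822 of the range), *HKDC1* (lowest, 0.778), *PI3* (highest, 0.732), the hair follicle (lowest, 0.712), sweat gland (lowest, 0.771) and type 2 axis lists (lowest, 0.797) and the type 1 axis list (highest, 0.780). In dysplastic nevi it held, always for the highest sample, for the type 2 axis (0.750), B cell and plasma cell (0.649), neutrophil (0.572) and type 17 axis lists (0.599). In normal skin the lowest sample stood apart for *CD274* (0.665), *ETV5* (0.702), *FBN1* (0.674), *PCOLCE2* (0.668), *PTGIS* (0.754) and the fibroblast list (0.630). There the highest stood apart for *CD3D* (0.638), *FAR2* (0.774), *IGSF11* (0.690), *KRT77* (0.715), *SLC45A2* (0.771) and the sebaceous gland (0.796), activated keratinocyte (0.653) and type 1 axis lists (0.728).

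The macrophage and monocyte list was higher in melanomas than in common nevi by 1.54 and than in dysplastic nevi by 0.88. The data argue against 3' bias of the labelling, since with the 3' to 5' difference as a covariate the list still differed by 1.51 (95% interval 0.97 to 2.05) and 0.88 (0.42 to 1.34). A lower share of melanocytic cells would raise the lists of other cell types alike. The macrophage list rose beyond the mean of the fibroblast, endothelium, cornified keratinocyte, sweat gland and smooth muscle lists by 1.38 and 1.30. Both gaps (exact permutation p = 0.000639 and 0.000163) argue against this as sole cause, but those lists moved both ways and set their size. Other effects of the labelling protocol cannot be told apart from the group, since melanomas alone had the standard protocol, and their hybridization control signal differed from each other group by -0.60 or more in size. More macrophages or a higher activity of them in melanoma, a difference the groups name, stays open and was not tested separately.

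The fibroblast and collagen matrix list differed by -1.32 between common nevi and normal skin (exact permutation p = 0.00649) and by -0.48 between dysplastic nevi and normal skin (exact permutation p = 0.0746; 0.0411 without dysplastic nevus replicate 5 and 0.00884 without normal skin replicate 4). Sliced sections against bulk biopsies cannot be told apart from the group: dysplastic nevi, prepared in the same way, had a list 0.84 above that of common nevi (exact permutation p = 0.0114), which did not pass over all lists (adjusted p = 0.104). Dilution by melanocytic cells cannot be told apart: the endothelium, macrophage, cornified keratinocyte, sweat gland and smooth muscle lists fell too, on average by 0.80 (exact permutation p = 0.0108), and the gap of the fibroblast list to them, -0.52, did not pass (exact permutation p = 0.197). This hangs on single nevi: without common nevus replicate 4 the fall was 0.48 (exact p = 0.0476) and the gap -0.81 (exact p = 0.0286), and without replicate 1 the gap was -0.30 (exact p = 0.433). A difference in stroma between the kinds of nevi and normal skin stays open.

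Between dysplastic and common nevi, camera called 19 lists although 3 genes were changed. A single nevus is a candidate explanation for the size of this count, which was 10 without common nevus replicate 1 and 12 without dysplastic nevus replicate 5, and so are the common nevi of another title scheme, without which, with the nevi of high control signal as a block, it was 4. The nevi of high control signal alone are argued against, since the count was 18 with them as a block and 16 without them. Of 100 splits of the 12 nevi 8 called as many lists (highest other 24) and 4 changed as many genes (highest other 44 against 3). Of 100 within the sets of nevi, with the block, 2 called as many lists (18, highest other 19) and 1 changed as many genes (5, highest other 3). Only lists without the block exceed 0.05, with genes close. The block was chosen on these data, and the splits ignore title schemes. Chance and what sets the nevi apart stay open.

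In the other comparisons only the real split, 1 of 100 (the lowest possible), had as many changed genes. The real count and the highest of the other splits were 522 and 49 for melanoma against common nevi, 249 and 5 against dysplastic nevi, 283 and 14 for common nevi against normal skin, 35 and 12 for dysplastic nevi against normal skin, and 958 and 641 for melanoma against normal skin. For the lists called by camera chance is not excluded: 9 splits had as many for melanoma against common nevi (24, highest other 29), 6 against dysplastic nevi (25, highest other 28), 22 for common nevi against normal skin (12, highest other 16), 23 for dysplastic nevi against normal skin (11, highest other 23) and 14 for melanoma against normal skin (23, highest other 30). The stepwise count was 0 in all 100 splits, so it decides nothing. These splits take no account of the nevi of high control signal.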

How the results depend on the processing

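No paired analysis was possible because the labels number the nevi and normal skin samples by other schemes than the melanomas and name no shared donor or batch. The exact permutation of list scores and the leaving out of melanomas with low melanocyte scores and all fits that concern the nevi of high control signal or the title scheme were chosen after seeing the data. Of 277 changed gene results that the naming rule gave, 140 lost their call under at least 1 alternative: 99 with a sample left out and 122 under another setting. Of the 173 that the text names, 80 did, and of the 104 others 60. None of them reversed. *CTLA4*, unchanged between melanomas and common nevi (-0.01), turned to 1.84 with the probe set of highest SD. With a median shift, quantile normalization, no filter, or trend and robust variance, each gene count stayed within 1.5 times its value. The cause of the changes below was not tested, except where fewer samples, more probe sets or no fold minimum change the count by construction.

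With the nevi of high control signal as a block, higher and lower genes numbered 10 and 8 for common nevi against normal skin, 7 and 6 for dysplastic nevi against normal skin, and 2 higher for dysplastic against common nevi, and 1 was stepwise higher. Without these nevi they numbered 28 and 20, 0 and 1, and 0 and 0, and 67 were higher in melanoma than in dysplastic nevi. Lists called for melanoma against dysplastic nevi were 16 with the block and 13 without these nevi. With the block and without the common nevi of another title scheme, dysplastic against common nevi gave 4 higher and 0 lower genes and 4 called lists, and the camera direction of the dendritic cell and the immediate early and heat shock lists was -1 where it had been up, at no difference (adjusted p = 0.923 and 0.955, list scores -0.03 and 0.03), so no reversal is shown.

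Camera with an estimated correlation called 0 lists in each comparison. Fry called 0 for dysplastic against common nevi, 14 for melanoma against dysplastic nevi, and 5 and 1 for common and dysplastic nevi against normal skin. Exact permutation called 0, 12 and 4 for dysplastic against common nevi, melanoma against dysplastic nevi and dysplastic nevi against normal skin. For dysplastic against common nevi, higher genes numbered 2 with the probe set of highest SD, with every probe set and with the covariate, 0 in a fit of the groups alone and 3 with no fold minimum, while lower genes numbered 1 with a minimum of 6, array weights or the covariate, 0 with the groups alone and 4 with no fold minimum. For dysplastic nevi against normal skin, counts were 154 higher and 47 lower with the groups alone, 121 and 29 with array weights, 36 and 20 with every probe set, 36 and 22 with no fold minimum, and 5 lower with a minimum of 6. With every probe set, melanoma against common nevi gave 615 higher and 269 lower, melanoma against dysplastic nevi 204 lower, common nevi against normal skin 234 and 215, and melanoma against normal skin 878 and 742. With no fold minimum these comparisons gave 1461 and 842, 773 and 527, 347 and 296, and 2614 and 1801. With the covariate, common nevi against normal skin had 100 higher genes, and 1 gene was stepwise higher. The 3' to 5' difference with *GAPDH* alone was -0.14 for melanoma against dysplastic nevi and 0.0166 for dysplastic nevi against normal skin, and with the middle probe sets 0.00249 for melanoma against normal skin.

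With each sample left out in turn, higher and lower genes ranged from 1 to 18 and 1 to 5 for dysplastic against common nevi, 306 to 431 and 108 to 178 for melanoma against common nevi, 76 to 139 and 93 to 168 against dysplastic nevi, 65 to 259 and 55 to 236 for common nevi against normal skin, 3 to 39 and 2 to 18 for dysplastic nevi against normal skin, and 478 to 598 and 363 to 466 for melanoma against normal skin. Stepwise genes ranged from 0 to 1 in each direction. Lists called ranged, in the same order, from 10 to 20, 23 to 27, 20 to 27, 11 to 17, 9 to 15 and 21 to 26. Genes with a log2 value of at least 4 in fewer than 5 samples were not tested, so changes among them are out of reach.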

Other observations

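Further gene lists fixed before the data were examined had higher scores in melanomas than in each of the other groups, though not all of these differences passed without the nevi of high control signal, an alternative chosen after seeing the data. The growth arrest and senescence list was higher by 0.60 ± 0.11, permutation adjusted p = 0.0137 against common nevi, by 0.48 ± 0.10, permutation adjusted p = 0.0241 against dysplastic nevi and by 0.70 ± 0.10, permutation adjusted p = 0.00888 against normal skin, with camera adjusted p between 0.0213 and 0.0261 and adjusted p between 0.26 and 0.462 with estimated correlation. Its changed members, 3, 2 and 4 of 12 measured, included the cell cycle inhibitor *CDKN2A* against normal skin alone (1.02 ± 0.33). The others were the secreted inflammatory factors *CXCL8* (1.77 ± 0.45, 1.36 ± 0.40 and 1.45 ± 0.42) and *IL6* (1.08 ± 0.31, 1.10 ± 0.27 and 1.07 ± 0.29), and the stress-induced cytokine *GDF15*. It rose by 2.51 ± 0.83 against common nevi and 2.79 ± 0.77 against normal skin. The type 17 axis list, which shares *CXCL8*, was higher by 0.58 ± 0.09, permutation adjusted p = 0.00201, 0.47 ± 0.08, permutation adjusted p = 0.0156 and 0.56 ± 0.08, permutation adjusted p = 0.00165, and passed camera against dysplastic nevi alone (adjusted p = 0.0331, and adjusted p = 0.303 with estimated correlation). For costimulation the differences were 0.68 ± 0.10, permutation adjusted p = 0.00529, 0.50 ± 0.13, permutation adjusted p = 0.0241 and 0.62 ± 0.11, permutation adjusted p = 0.00888 (camera adjusted p = 0.000654, 0.00441 and 0.0263, and adjusted p = 0.26, 0.316 and 0.462 with estimated correlation), with the T cell receptor *ICOS* up by 1.46 ± 0.36 against common nevi and 1.71 ± 0.33 against normal skin. Inflammasome and innate sensing scores differed by 0.46 ± 0.09, permutation adjusted p = 0.00529, 0.28 ± 0.07, permutation adjusted p = 0.0403 and 0.42 ± 0.08, permutation adjusted p = 0.00888 (camera adjusted p = 0.000362, 0.00752 and 0.00998, and adjusted p = 0.26, 0.316 and 0.462 with estimated correlation), with the DNA sensor *AIM2* up by 1.40 ± 0.30 and 1.14 ± 0.28. Without the nevi of high control signal, the permutation adjusted p of the growth arrest list was 0.0635 against common nevi (difference 0.59), where the other 3 lists passed (0.0423 each). Against dysplastic nevi none of the 4 passed, with growth arrest at 0.48 (adjusted p = 0.0958), type 17 at 0.44 (0.0907), costimulation at 0.38 (0.125) and inflammasome at 0.27 (0.121). The calls of *CXCL8* against dysplastic nevi were lost without dysplastic nevus replicate 1, 2, 3, 4, 5 or 6 (adjusted p between 0.0502 and 0.0676). *IL6* lost its call against common nevi without common nevus replicate 2 (adjusted p = 0.0573) or melanoma replicate 15 (difference 0.99), and against normal skin without melanoma replicate 8, 12, 13 or 15 (differences between 0.98 and 1.00, under 2-fold). *GDF15* lost its call against common nevi in 10 of the 21 fits that left out 1 sample (adjusted p up to 0.101), in a fit of these groups alone (0.122) and with array weights (0.119). *CDKN2A* came under 2-fold in 6 of the 22 fits (down to 0.89) and with array weights (0.94). With array weights *CXCL8* did not pass against common (adjusted p = 0.0706) or dysplastic nevi (0.0567), nor *IL6* against common nevi (0.0597). In a fit of the groups alone *CXCL8* did not pass against dysplastic nevi (0.0803), nor *IL6* against common nevi (0.0752), and *IL6* was under 2-fold against normal skin without the melanomas of low melanocyte score (0.99).

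In 2 of 16 melanomas the melanocyte score was below every normal skin sample. Without these 2, an alternative chosen after seeing the data, each pairwise count of the melanoma comparisons stayed within 1.5 times its value, and *PMEL* rose by 2.28 against common nevi (adjusted p = 0.00059).

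Across the 16 melanomas, 7 relations between list scores were tested, all chosen after the group comparisons were seen, with permutation p values and Benjamini-Hochberg adjustment over the 7. The hypothesis was that immune lists vary together between melanomas. T cell scores rose with macrophage scores (Pearson r = 0.758, permutation p = 0.0007, adjusted p = 0.00122; Spearman rho = 0.674, p = 0.0055), with type 1 axis scores (r = 0.888, p = 2e-05, adjusted p = 0.00014; rho = 0.853, p = 8e-05) and with type I interferon scores (r = 0.777, p = 0.00063, adjusted p = 0.00122; rho = 0.859, p = 6e-05). Type 1 axis scores rose with checkpoint scores after the 1 shared gene was left out (r = 0.864, p = 4e-05, adjusted p = 0.00014; rho = 0.774, p = 0.00063). Without the 2 melanomas farthest from the median of the measure named before the other, these r values were 0.751, 0.877, 0.862 and 0.813. T cell scores showed no relation that passed with melanocyte lineage scores (r = -0.12, p = 0.647, adjusted p = 0.647; rho = -0.03, p = 0.917; r = 0.166 without the 2 farthest) or proliferation scores (r = 0.164, p = 0.539, adjusted p = 0.628; rho = 0.262, p = 0.323; r = 0.360 without them), nor did macrophage scores with fibroblast scores (r = 0.352, p = 0.182, adjusted p = 0.254; rho = 0.271, p = 0.309; r = -0.02 without them). A shared immune infiltrate that differs in size between melanomas is a candidate explanation of the relations that passed (r between 0.758 and 0.888), found and tested on the same samples. The labels give no batch or date within the melanomas, so the relations could not be recomputed within one.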
